A study of Rattus norvegicus with 44 samples.

How the data were processed

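Polyadenylated RNA was sequenced from CA1 and the dentate gyrus (DG), dissected from 1 hippocampus of each of 22 male rats, which gave 44 libraries. Per the labels, 8 young rats received saline (young vehicle), 8 young rats received the bacterial endotoxin lipopolysaccharide at 1 mg per kg (young LPS) and 6 aged rats received saline (aged vehicle). Injections were given weekly for 7 weeks, and tissue was taken 48 hours after the last one. Libraries were made with an Ion Torrent total RNA kit, per the labels' protocols. Groups and animal numbers were taken from the sample labels.

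The authors deposited 1 table of normalized read counts for each region, a signal that is never negative, with 20003 rows for CA1 and 20050 for DG, of which 19882 were shared. STAR, Partek, DESeq2 and genome build rn6 are named, per the submitters' processing notes, with no versions or roles; the annotation, the read filters and the use of strand are not given in the sources used here. In the deposited values each library's numbers are whole multiples of a single step, the value of 1 read, which ran from 0.818 to 1.46 in CA1 and from 0.659 to 1.32 in DG. Dividing by it, within a tolerance of 0.1, gave whole reads for 99.75% of values in CA1 and 99.98% in DG; fractions occurred in 240 and 11 rows. Recovered totals ran from 12292346 to 18749663 reads per library in CA1 and from 12130182 to 23519791 in DG. Counting error covers only the sampling of reads. The tables were normalized separately, so levels were tested only within a region. Gene symbols are those of the deposited tables.

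Genes with a value of at least 10 in at least 6 libraries of a region were tested, 14915 in CA1 and 14904 in DG. Tests used limma 3.58.1 (R 4.3.3) with the trend and robust options on log2(value + 1), all 3 groups in 1 fit per region, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. The number of genes that chance gives at an unadjusted p below 0.05 is an average. Genes are not independent, so single groupings scatter widely around it. Regroupings of the LPS and aged CA1 libraries without aged replicate 2532 gave a median of 450 and a highest count of 4456, where the average is 746. Other such counts were not set against regroupings. The comparisons were young LPS minus young vehicle, aged vehicle minus young vehicle, and young LPS minus aged vehicle. Of 39 gene lists, for cell types, immune and stress responses, synapses, mitochondria and senescence, 38 in CA1 and 36 in DG had at least 5 tested genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists, groups, tests, rule for named genes and most alternatives were fixed before the data were examined.

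Genes are named by that rule. In each comparison it takes, among genes past the threshold with a symbol, the 6 largest and 6 smallest log2 changes (all where fewer pass), then 3 members of each called list in its direction and 1 against it by smallest p, then 9 preset genes (8 with a row in the CA1 table), up to 30 genes. Il1b fell below the filter in both regions; Cd74 in CA1 was not analysed here. For LPS in CA1, 1 gene that the rule takes is not reported here.

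Whether an effect differed between the regions was tested with limma on the difference CA1 minus DG within each rat, a block by animal. The pairing comes from the labels: both regions came from 1 hippocampus, and the titles carry the rat's number. Deviations of the same rat's libraries from their group means had a median correlation across genes of 0.051, above 0.1 in 8 of 22 rats, and 1 rat's CA1 library correlated best with its own DG library. Random pairing gives about 1 such rat, so this count adds no evidence for the pairing beyond the labels. Differences of list means between regions were tested by exact permutation of the rats. The likeness of the LPS and age effects was given as a correlation across genes, beside 1000 reassignments of group-centred libraries and all 70 splits of the shared young vehicle libraries.

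The procedures were tested on simulated data. With LPS effects added to about 200 genes, limma recovered 18% of changes of 0.5 on the log2 scale in CA1 and 50% in DG, 82% and 88% of changes of 1, and 98% and 100% of changes of 2. For the region difference it recovered 38% of differences of 1 and 89% of differences of 2. Simulated genes were drawn independently of one another and no library deviated, so these shares may not hold for the data. No replicate pair within a group differed by so little as counting noise: the lowest chi-square per gene was 4.57 in CA1 and 6.62 in DG. The alternatives covered the pseudocount (5 and 0.25), the filter (none, or a mean of at least 50), TMM scaling, the groups in the fit, library weights, the number series of the rats (the leading digits of the animal number, 24, 25 or 27), a dissection score (CA1 pyramidal minus dentate granule markers), edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma without its trend and robust options, each library of the compared groups left out and, chosen after seeing the data, each library of the third group and libraries of low correlation or of a meningeal fibroblast list mean over 1 above the region's mean. The number series lay unevenly over the groups. Replicate 2410 was the only young vehicle rat of series 24, 2531 and 2532 were the only aged rats of series 25, and series 27 held no aged rat. The deposited list of library names was not used.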

Results

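Gene expression was measured in CA1 and DG of young rats given saline (n = 8), young rats given LPS, an endotoxin that provokes inflammation outside the brain (n = 8), and aged rats given saline (n = 6). Young rats were 5 to 7 months old. Aged rats were 14 to 16 months old. Libraries held between 12130182 and 23519791 recovered reads. The series set out 3 comparisons in each region: LPS treatment, age, and young LPS against aged vehicle.

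In DG of rats given LPS, C3, the central component of the complement cascade, was higher. Rpl6, which encodes a protein of the large ribosomal subunit, was lower. C3 was 996 ± 320 (SD, n = 8) normalized reads in young LPS and 472 ± 89.9 (SD, n = 8) in young vehicle, a log2 change of 1.03 (SE 0.16, limma adjusted p = 0.00595). The LPS libraries ran from 661 to 1417 and the vehicle libraries from 337 to 605, so the groups did not overlap, as for 6 genes in DG, where chance gives 2.32. Rpl6 was 1354 ± 146 (SD, n = 8) in young LPS and 2214 ± 455 (SD, n = 8) in young vehicle, a log2 change of -0.69 (SE 0.11, limma adjusted p = 0.00595), lower in 8 of 8 LPS libraries than the vehicle median. In CA1 Rpl6 was 1985 ± 657 (SD, n = 8) in young LPS and 1620 ± 601 (SD, n = 8) in young vehicle, a log2 change of 0.32 that did not pass. CA1 minus DG was 1.01 (SE 0.30, limma adjusted p = 0.351 over all genes, with the rat as block), so the difference between regions did not pass either. Ribosomal protein genes have processed copies elsewhere in the genome, and how the counting treated shared reads is not given, so this change is uncertain in origin. These were the 2 genes called by limma in DG, and 1122 reached an unadjusted p below 0.05, where chance gives about 745 on average. edgeR called 2 and DESeq2 3. With the number series of the rats in the fit, the changes were 0.94 for C3 and -0.72 for Rpl6 (limma adjusted p = 0.00783 for both).

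**Figure D1:**
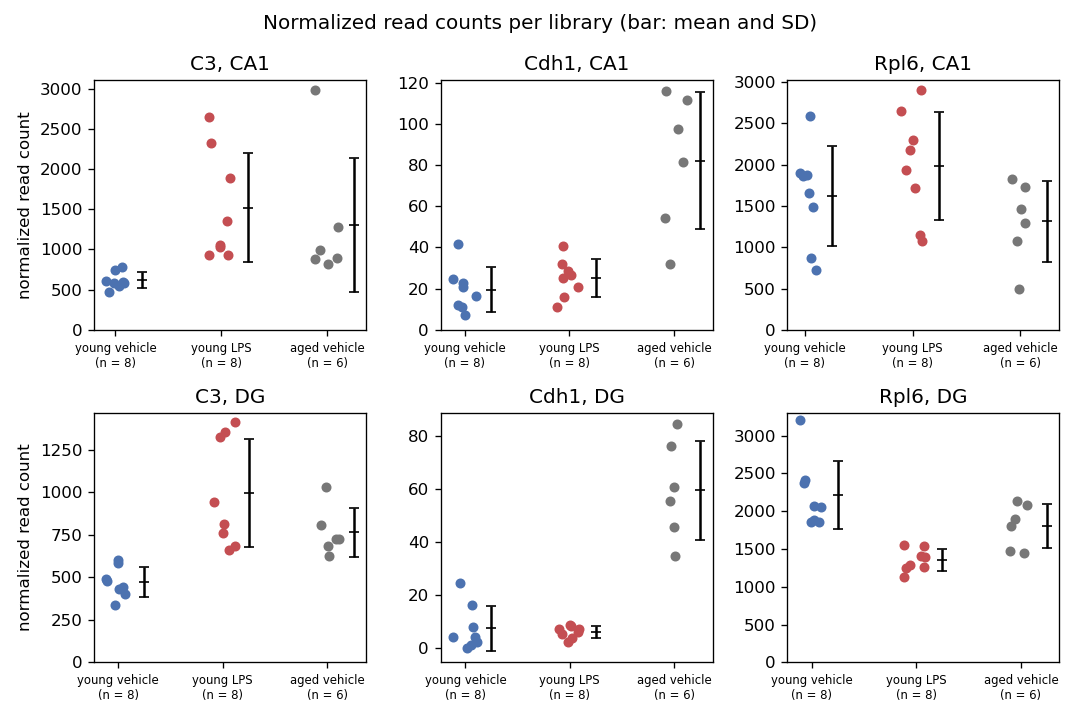
Normalized read counts of C3, Cdh1 and Rpl6 (vertical axis, starting at or just below 0) in CA1 (top) and DG (bottom) for young vehicle, young LPS and aged vehicle rats (horizontal axis). Each point is a library, the bar gives the mean and SD, and C3 in DG lies between 661 and 1417 in the LPS libraries, above the young vehicle libraries (337 to 605) and overlapping the aged ones (624 to 1032).

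In CA1, LPS gave no gene past the threshold with limma. An unadjusted p below 0.05 was reached by 1024 genes, where chance gives about 746 on average. Single groupings scatter widely around that number, so the excess does not exclude chance. In this comparison edgeR called 0 and DESeq2 1. C3 was 1522 ± 680 (SD, n = 8) in young LPS and 615 ± 101 (SD, n = 8) in young vehicle. Its log2 change was 1.20 (SE 0.24, limma adjusted p = 0.615), and the groups did not overlap, with LPS libraries from 930 to 2651 and vehicle libraries from 474 to 779. With DESeq2 the adjusted p of C3 was 0.00399, and over 36 alternatives it ran from 0.00399 to 0.906; C3 also passed without aged replicate 2420 (limma adjusted p = 0.0332). Without overlap stood 2 genes in CA1, no more than the 2.32 of 14915 that chance gives. The C3 effect did not differ detectably between the regions: CA1 minus DG was 0.17 (SE 0.23, limma adjusted p = 0.737 over all genes, with the rat as block).

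Of the preset genes, Gfap, the intermediate filament of astrocytes, was 25154 ± 5474 (SD, n = 8) in young LPS and 21503 ± 6614 (SD, n = 8) in young vehicle in CA1 (log2 change 0.25, limma adjusted p = 0.654). In DG it was 17185 ± 1446 (SD, n = 8) and 18130 ± 4631 (SD, n = 8), a log2 change of -0.043 (limma adjusted p = 0.954). The microglial gene Aif1 had a log2 change of -0.30 in CA1 and 0.17 in DG, the endotoxin receptor gene Tlr4 0.18 and 0.011, the cell cycle inhibitor gene Cdkn1a 0.38 and -0.18, the neurotrophin gene Bdnf -0.33 and -0.07, and the NMDA receptor subunit gene Grin2b 0.04 and -0.03. None of these passed. Cd74, the invariant chain of MHC class II, was 427 ± 147 (SD, n = 8) in young LPS and 288 ± 157 (SD, n = 8) in young vehicle in DG (log2 change 0.63, limma adjusted p = 0.598).

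Among gene lists in CA1, those of myelinating oligodendrocytes (camera adjusted p = 0.0384), astrocytes (0.0384) and blood cells (0.0425) were higher with LPS at the preset correlation. Each had adjusted p = 0.795 with an estimated correlation. Of 100 splits of the rats, the real one included, 84 gave as many called lists, so chance is not excluded. No member of the 3 lists rose over all genes tested; 1 astrocyte gene did when adjusted over the list alone, and 0 in the others. Of 23 oligodendrocyte genes 18 had a positive change, such as the carbonic anhydrase gene Car2 (0.24) and the myelin regulatory factor gene Myrf (0.35), against Aspa (-0.31). Of 16 astrocyte genes 13 did, such as the amino acid transporter gene Slc7a10 (0.44), Fgfr3 (0.25) and Ntsr2 (0.30), against the water channel gene Aqp4 (-0.15). All 5 blood genes did, such as the haem synthesis gene Alas2 (0.95), Hba-a2 (0.76) and LOC103694857 (0.68). All 3 calls ended with the number series of the rats in the fit (adjusted p = 0.0770 for oligodendrocytes, 0.218 for astrocytes and 0.236 for blood cells), and with the dissection score (0.237 for astrocytes and for blood cells), where the oligodendrocyte list turned downward (adjusted p = 0.921). The call was lost without any one of 8 libraries for oligodendrocytes, 8 for astrocytes and 10 for blood cells, among them aged replicate 2532, which shares the fit. The mean change of the oligodendrocyte list was 0.16, but 0.10 without 2403, 0.091 without 2404, 0.098 without 2410 and 0.10 without 2722, and that of the astrocyte list 0.14, but 0.087 without 2404.

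In DG the interneuron list was higher with LPS (camera adjusted p = 0.00202; adjusted p = 0.953 with an estimated correlation), with 13 of 17 members positive. Of these, 0 rose over all genes and 2 when adjusted over the list alone. Dlx1, a transcription factor of GABAergic neurons, had a log2 change of 0.52, the GABA synthesis gene Gad2 0.29 and Nxph1 0.31, against Lhx6 (-0.23). The list call was lost without replicate 2728, and with the number series of the rats in the fit (adjusted p = 0.10). Of 100 splits of the rats, the real one included, 98 gave as many called lists, so chance is not excluded.

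Cdh1, which encodes the adhesion protein E-cadherin, was higher in aged rats in both regions. In DG it was 59.7 ± 18.7 (SD, n = 6) in aged and 7.54 ± 8.59 (SD, n = 8) in young vehicle rats, a log2 change of 3.43 (SE 0.52, limma adjusted p = 0.00359). In CA1 it was 82.2 ± 33.2 (SD, n = 6) and 19.5 ± 10.9 (SD, n = 8), a log2 change of 2.06 (SE 0.35, limma adjusted p = 0.0260). CA1 minus DG was -1.37 (SE 0.59, limma adjusted p = 0.735 over all genes, with the rat as block). In CA1 the homeobox gene Pbx3 also rose, from 287 ± 45.4 (SD, n = 8) to 602 ± 93.7 (SD, n = 6), a log2 change of 1.07 (SE 0.18, limma adjusted p = 0.0260). In DG AABR07001734.1, a row without a symbol named after its values were seen, rose by 2.18 (SE 0.33, limma adjusted p = 0.00359).

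These were the 2 age calls in each region. With age, 1882 genes in CA1 reached an unadjusted p below 0.05, where chance gives about 746 on average. In DG 446 did, fewer than the 745 that chance gives on average. edgeR called 2 in each region, and DESeq2 7 in CA1 and 4 in DG. The 2 CA1 calls ended (0 genes) without any one of replicates 2411, 2412, 2415, 2420, 2410, 2523, 2571, 2572, 2722 and 2731. In DG the count was 2 or 3 with each library left out. With the number series of the rats in the fit, Cdh1 had a change of 2.96 in DG (SE 0.59, limma adjusted p = 0.203) and 1.61 in CA1 (SE 0.37, 0.248), and Pbx3 0.96 (SE 0.20, 0.248), so these calls ended, with smaller changes and larger errors.

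C3 was also higher in aged rats, at 1307 ± 837 (SD, n = 6) in CA1 (log2 change 0.93, limma adjusted p = 0.393) and 766 ± 143 (SD, n = 6) in DG (0.70, limma adjusted p = 1.00), and neither passed. Gfap in DG was 21855 ± 2724 (SD, n = 6) in aged and 18130 ± 4631 (SD, n = 8) in young vehicle rats (log2 change 0.30, limma adjusted p = 1.00). In CA1 the changes of Gfap (0.05), Aif1 (0.22), Tlr4 (0.47), Cdkn1a (-0.10), Bdnf (-0.07) and Grin2b (-0.41) did not pass. Cd74 in DG had a change of 0.63 and did not pass.

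In CA1 the list of nuclear genes of oxidative phosphorylation was lower in aged rats (camera adjusted p = 6.73e-05; adjusted p = 0.857 with an estimated correlation), with 59 of 74 members negative, such as the complex I genes Ndufa13 (-0.56), Ndufc1 (-0.43) and Ndufs8 (-0.33), against Ndufs1 (0.44). Aged replicate 2532 had a list mean of -0.54 relative to all CA1 libraries, while the other 5 aged libraries ran from -0.18 to 0.07. The mean change of the list was -0.18 with that library and -0.095 without it, and the call ended without 2532 and 2572 (adjusted p = 0.0583). In 2532 genes with ribosomal protein symbols held 0.534% of the normalized reads, the lowest of the CA1 libraries (other aged libraries 0.782% to 0.909%), and the list mean of mitochondrially encoded genes was 0.59, second to vehicle 2572 (1.07). The interferon response list was higher (0.00359; adjusted p = 0.857 with an estimated correlation), with 30 of 36 members positive, such as Ddx58 (0.47), Gbp2 (0.55) and Ifi47 (0.75), against Ifitm1 (-1.11). The microglial activation list was higher (0.0335; adjusted p = 0.857 with an estimated correlation), with 15 of 18 positive, such as the IgG receptor genes Fcgr2b (0.99) and Fcgr3a (0.71) and the osteopontin gene Spp1 (0.64), against Apoe (-0.37). The reactive astrocyte list was higher (0.0335; adjusted p = 0.857 with an estimated correlation), with 15 of 22 positive, such as Ggta1 (0.57), the oncostatin M receptor gene Osmr (0.98) and Gbp2, against Slc10a6 (-0.50). No member of these lists passed over all genes tested; adjusted over the list alone, 3 microglial and 1 reactive astrocyte gene rose and 0 of the others changed. The 3 calls of higher lists ended with the number series of the rats in the fit (adjusted p = 0.0617 for interferon, 0.537 for microglial activation and 0.126 for reactive astrocytes), and the last 2 of these also with the dissection score (0.0817 and 0.115). The interferon call was also lost without replicate 2420, the microglial call without any one of 7 libraries and the reactive astrocyte call without any one of 8, with a mean change of 0.22 that was 0.14 without 2532. Aged replicate 2420 had list means of 0.59 for interferon, 0.52 for microglial activation and 0.61 for complement, and the highest choroid plexus mean of the aged libraries (1.32). Vehicle 2526 had 0.73 for interferon and 3.83 for choroid plexus, a list whose mean change with age was -0.11 (camera adjusted p = 0.803). As many lists as the 4 called here came from 74 of 100 splits of the rats, the real one included, so chance is not excluded.

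In DG 7 lists were called with age. As many came from 61 of 100 splits of the rats, the real one included, so chance is not excluded. Interneurons (camera adjusted p = 0.000320, 14 of 17 positive), microglial activation (0.00115, 14 of 18), MHC class II presentation (0.00115, 7 of 9), complement (0.00128, 14 of 17) and CA1 pyramidal neurons (0.0486, 9 of 10) were higher. Oligodendrocyte precursors (0.0416, 9 of 11 negative) and endothelial cells (0.0446, 14 of 16 negative) were lower. With an estimated correlation the adjusted p was 0.756 for interneurons, 0.930 for endothelial cells and 0.812 for the others. No member passed over all genes; adjusted over the list alone, 1 microglial and 1 complement gene rose. Examples were Dlx1 (0.37), Reln (0.27) and Gad2 (0.19) against Calb2 (-0.28) for interneurons, and Fcgr2b (0.74), Gpnmb (0.50) and Ctsz (0.47) against Axl (-0.12) for microglia. RT1-Db1 (1.27), the cathepsin gene Ctss (0.30) and Cd74 stood against Ifi30 (-0.09), and C3, Itgb2 (0.35) and C4a (0.67) against C3ar1 (-0.15). The CA1 pyramidal genes Wfs1 (1.20), Fibcd1 (0.85) and Gpr161 (0.76) stood against Zfpm2 (-0.18), and that list turned downward with the dissection score in the fit (adjusted p = 0.453). For precursors Neu4 (-0.46), C1ql1 (-0.32) and Tnr (-0.16) stood against Bcas1 (0.29), and for endothelium Itm2a (-0.19), Egfl7 (-0.27) and Kdr (-0.30) against Emcn (0.03). Of these 7 calls, 6 ended with the number series of the rats in the fit. The endothelial call stayed (adjusted p = 0.00186), and the adjusted p of the others ran from 0.242 for MHC class II to 0.856 for complement. The complement call also ended with the dissection score (0.0669). The microglial call was lost without replicate 2532, the precursor call without any one of 5 libraries, the endothelial call without any one of 9 and the CA1 pyramidal call without any one of 11. The mean change of the microglial list was 0.18, but 0.091 without 2532, and that of the complement list 0.22, but 0.14 without 2532 and 0.33 without 2572. It was -0.10 for precursors, but -0.061 without 2411, and 0.52 for CA1 pyramidal neurons, but 0.79 without 2531.

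Vascular and meningeal markers stood high in the same 3 DG libraries. Relative to all DG libraries, the means in young vehicle replicates 2526 and 2572 were 1.76 and 2.11 for meningeal fibroblasts, 0.98 and 0.89 for mural cells, 1.30 and 1.68 for perivascular macrophages and 0.53 and 0.65 for endothelial cells. In aged replicate 2532 they were 1.85, 0.43, 1.28 and 0.37. In 2526, 2572 and 2532 the mean was 0.57, 0.78 and 0.59 for complement, the highest of the DG libraries, and 0.59, 0.71 and 0.80 for MHC class II presentation (LPS 2408 had 0.60). It was 0.14, 0.38 and 0.52 for microglial activation (0.30 in 2408) and -0.20, -0.20 and 0.098 for the TLR4 pathway. The mean change of the endothelial list with age was -0.12, but -0.046 without 2526, -0.029 without 2572, -0.050 without 2531 and -0.20 without 2532. Without these 3 libraries of high meningeal fibroblast mean, a choice made after seeing the data, it was -0.021 and the call ended (adjusted p = 0.775). Without the 2 vehicle libraries alone it turned to 0.066 (adjusted p = 0.217), and the precursor call ended (0.0862). Also without those 2, the change went from 0.22 to 0.45 for complement, from 0.43 to 0.72 for MHC class II and from 0.18 to 0.29 for microglial activation; without all 3 it was 0.37 for complement. The CA1 pyramidal call ended without all 3 (0.108) and without the 2 (0.0530).

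Young LPS and aged vehicle rats differed in CA1 at 1302 genes, 521 higher and 781 lower in LPS. At an unadjusted p below 0.05 stood 5336 genes, where chance gives about 746 on average. Of the 1302, 1300 had an adjusted p between 0.045 and 0.05. Among the largest changes, B4gat1, a glycosyltransferase gene, was 103 ± 173 (SD, n = 8) in LPS and 0.67 ± 1.64 (SD, n = 6) in aged rats, of which 5 were at 0 (log2 change 3.88, limma adjusted p = 0.0490). Against a group almost wholly at 0 this change depends on the pseudocount and the tool, and it ran from 2.44 to 7.23 over the alternatives. The kinase gene Pak2 was 1.22 ± 1.52 (SD, n = 8) and 17.4 ± 10.1 (SD, n = 6) (log2 change -2.95, from -4.00 to -1.69 over the alternatives), and Fam122b 7.94 ± 9.26 (SD, n = 8) and 31.8 ± 8.70 (SD, n = 6) (-2.67). The others by the rule were Gpr173 (2.997, from 1.63 to 5.72 over the alternatives, with 5 of 6 aged libraries at 0), the chloride channel gene Clcn2 (1.70), Lrrc29 (1.42, from 0.85 to 1.80), Ifitm1 (1.39, from 0.80 to 1.80) and the precursor receptor gene Gpr17 (1.17), which were higher in LPS, and Cdh1 (-1.64), Fbxo5 (-1.54), Rpa3 (-1.38) and the replication inhibitor gene Gmnn (-1.36), which were lower. Each had limma adjusted p = 0.0490. C3 had a change of 0.27, Aif1 -0.53, Cdkn1a 0.47, Grin2b 0.45, Gfap 0.20, Tlr4 -0.29 and Bdnf -0.26, and none passed.

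The CA1 count rested on single libraries. It was 0 without any one of aged replicates 2420, 2531 and 2532 or LPS replicates 2404, 2408, 2527 and 2717, 1 without 2543 and 2 without 2415, and it was 3399 without 2411, 2631 without 2403 and 2245 without 2573. Aged replicate 2532 had a median correlation of 0.908 with the other CA1 libraries, while the next lowest aged library had 0.978. Without 2532 and 2572, the pair of lowest median correlation, 4 genes were called. Vehicle libraries, outside the comparison but in the same fit, were left out as a choice made after seeing the data. The count was then 2 without any one of 2410, 2526, 2571, 2728 and 2731, 1 without 2722, 1898 without 2523 and 1787 without 2572. Replicate 2526 had the highest meningeal fibroblast mean in CA1 (1.45). No list passed in this comparison in CA1.

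In DG 2 genes differed between young LPS and aged vehicle. Cdh1 was lower in LPS, at 6.23 ± 2.24 (SD, n = 8) against 59.7 ± 18.7 (SD, n = 6) (log2 change -3.08, SE 0.52, limma adjusted p = 0.0369), and AABR07068154.1, named after its values were seen, was higher (0.76, SE 0.13, limma adjusted p = 0.0369). At an unadjusted p below 0.05 stood 1356 genes, where chance gives about 745 on average. There edgeR called 1 and DESeq2 22. Of the 14 libraries compared, the count was 0 without any one other than 2532 (1 gene) and 2547 (3 genes). With a vehicle library left out it was 0 without 2571, 1 without 2410 or 2731 and 2 without any one of the other 5. The complement list was lower in LPS (camera adjusted p = 0.00459; adjusted p = 0.874 with an estimated correlation), with 15 of 17 members negative, such as C4a (-1.05), C4b (-1.15) and C1qc (-0.35), against C3 (0.33). None passed over all genes tested and 1 fell when adjusted over the list alone. The call was lost without 2532 and with the number series in the fit (adjusted p = 0.222). As many called lists came from 95 of 100 splits of the rats, the real one included, so chance is not excluded. Gfap (-0.34), Aif1 (0.18), Cd74 (0.0015), Tlr4 (-0.30), Cdkn1a (-0.22), Bdnf (0.02) and Grin2b (0.31) did not pass.

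The log2 changes with LPS and with age correlated across the 14915 genes of CA1 at r = -0.07 (Spearman rho = -0.21), where reassigned unchanged groups against the shared young vehicle libraries gave a median of 0.49 (central 95% from 0.042 to 0.76). The covariance was -0.00553 against a simulated mean of 0.0269. With the controls split the median r was -0.28. The sign of r in CA1 rested on single libraries. It was 0.18 without aged replicate 2532, 0.010 without 2404, 0.023 without 2543 and 0.041 without 2526. Without any one of the others r was negative (lowest -0.17). The 0.18 lies inside the simulated range, but that range was drawn with 2532 in and not redrawn without it. In DG r was 0.30 (rho = 0.26), within the simulated range of 0.16 to 0.69, the covariance 0.0153 against 0.0255, and r with split controls -0.14. Genes are not independent replicates. In neither region was the likeness of the effects above that from shared controls alone.

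For the difference of the LPS effect between regions 1 gene passed, the zinc finger gene Zfp300, which had a log2 change of -1.35 in CA1 and 0.44 in DG. CA1 minus DG was -1.79 (SE 0.29, limma adjusted p = 0.0407) with the rat as a block, and 0.316 was its adjusted p with no replicate block, so that 0 genes were called there. The call was lost with any one of 17 rats left out. Over all genes, 1900 had an unadjusted p below 0.05 for the LPS difference and 763 for the age difference. Chance gives about 732 for each on average, and single groupings scatter widely, so the excess does not exclude chance. For age none passed, and Trhr had the smallest p (CA1 minus DG 1.12, limma adjusted p = 0.614, not significant). None of 36 list means differed between regions by exact permutation of the rats (lowest adjusted p = 0.590 with LPS and 0.963 with age). With LPS in CA1 and DG, the mean changed by 0.088 and 0.18 for interneurons and 0.14 and -0.041 for astrocytes. It changed by 0.16 and 0.021 for myelinating oligodendrocytes and 0.69 and 0.084 for blood cells.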

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

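Of 156 groups of values examined for a single library far from the rest, 21 had one. Chance gives about 1 in 20 for normally distributed values. Genes were examined as normalized reads, and many were chosen for large changes, so that share need not hold here. The tests in this part were chosen after the results were seen, except those of blood and choroid plexus RNA and of single young vehicle libraries.

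In CA1 aged replicate 2532 had the lowest median correlation of its group (0.908) and its highest Rpa3 (155), Fbxo5 (37.9), Tlr4 (81.7) and Gpr173 (1.46), and in DG its highest Cdkn1a (86.7). Young vehicle replicate 2572 had the lowest median correlation (0.946) and the fewest detected genes (16280) of its CA1 group, and the highest mitochondrial percent of reads in CA1 (15.8) and DG (12.8). It also had the highest B4gat1 of the young vehicle CA1 group (42.2), and 2411 had the highest B4gat1 of the aged CA1 group (4.02). For Gpr173 and B4gat1 the nearest aged CA1 library was at 0, where the rule flags any value above 0. The Gpr173 value of 2532 is that of 1 read. The other single libraries in CA1 were C3 in aged 2420 (2983), Gpr173 in LPS 2543 (44.9) and vehicle 2722 (41.3), Grin2b in vehicle 2523 (3748), the astrocyte list mean in aged 2415 (-0.11) and the interferon list mean in vehicle 2526 (0.73). In DG they were Rpl6 in vehicle 2526 (3203), the interneuron list mean in vehicle 2410 (0.33) and the recovered reads of vehicle 2728 (22934253).

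Zfp300 passed the test of the LPS effect in CA1 against DG within rats (-1.79), but 6 of 100 splits of the rats gave as many genes, so chance is not excluded.

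The calls between young LPS and aged vehicle in CA1 could come from 1 deviating aged library. Without 2532 no gene passed, and the median change of the 1302 genes was 0.76 of its former size (quartiles 0.69 and 0.84), but those genes were chosen with it in the fit. At those genes 2532 lay a median of 0.83 past the other aged libraries, away from LPS, while LPS and those others differed by a median of 0.44. Over all genes 3676 still had an unadjusted p below 0.05 without 2532, where chance gives about 746 on average. Of 100 regroupings of the remaining libraries, the real one included, 2 gave as many (median of the others 450, highest 4456). That argues against 2532 as the whole source of the differences at an unadjusted p. It does not speak for the 1302 calls, none of which remained. Over the 1302 genes the median ratio was 1.02 with the dissection score in the fit and 1.08 with the number series, so neither reduced their changes. Those genes were chosen in the fit without these terms, so the ratios do not decide about either. Age and LPS, the groups of the design, stay open, as do dissection and the number series. The count itself stays open too, since it moved from 0 to 3399 with single libraries left out.

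The interneuron list in DG had a mean log2 change of 0.18 (SE 0.08) with LPS and 0.19 (SE 0.09) with age, both against the same 8 vehicle libraries. With the number series of the rats in the fit the age change was 0.036 (SE 0.076), so the number series may account for it, and the LPS change was 0.10 (SE 0.06), which leaves that open. Both list calls ended in that fit (adjusted p = 0.708 with age and 0.10 with LPS). With the dissection score the LPS change was 0.17 (SE 0.07), which argues against the balance of CA1 pyramidal and dentate granule tissue as its whole source. The age change was then 0.13 (SE 0.08), which decides nothing. The score measures only that balance, so other differences of dissection stay open. Of 100 splits of the rats, 98 gave as many called lists in DG with LPS and 61 with age. Chance is therefore not excluded, and there may be no change to explain. With 1 young vehicle library left out the lowest changes were 0.14 and 0.15, which does not decide.

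C3 was higher with LPS in both regions. With the blood list mean in the fit its change was 1.04 in CA1 and 1.03 in DG, and with the choroid plexus list mean 1.25 and 1.03, which argues against RNA of blood or choroid plexus as the whole source. With the number series it was 1.04 (SE 0.23) in CA1 and 0.94 (SE 0.16) in DG, which argues against the series in the same way. The choroid plexus list had 7 tested genes in CA1 and 2 in DG, so the DG test is weak. That LPS itself raised C3 in the hippocampus is a hypothesis, found and tested on the same data.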

How the results depend on the processing

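The alternatives without the libraries of lowest median correlation (2532 and 2572 in CA1, 2526 and 2547 in DG) and of high meningeal fibroblast mean (2526 in CA1; 2526, 2572 and 2532 in DG) were chosen after seeing the data, as was leaving out single libraries of the group outside a comparison. Of 504 recomputed group results 338 stayed the same, counts within 1.5 times and correlations within 1 jackknife SE. C3 and Rpl6 in DG with LPS kept their direction and passed in all 36 alternatives, with adjusted p from 2.76e-07 to 0.0323 and from 1.78e-06 to 0.0374. The cause of the changes below was not tested unless fewer genes or libraries entered.

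For young LPS against aged vehicle in CA1 the count was 3 without a filter, 0 with the 2 groups alone, 3496 with library weights, 2910 with the number series, 1998 with the dissection score, 2155 with edgeR, 3299 with DESeq2, 2 without trend and robust options and 4 without those libraries (0 to 3399 with single libraries left out). In DG it was 0 with a pseudocount of 0.25, without a filter and with the stricter filter, 4 with the 2 groups, 171 with weights, 8 with the number series, 1 with edgeR and 22 with DESeq2 (0 to 3 with single libraries out). The age count in CA1 was 1 with the stricter filter, with the 2 groups and without those libraries, 303 with weights, 0 with the number series or the dissection score and 7 with DESeq2 (0 to 3). In DG it was 0 with the stricter filter, 1 with the 2 groups or the number series, 8 with weights and 4 with DESeq2 or without trend and robust options (2 to 3). The LPS count in CA1 was 1 with DESeq2 (0 to 1), and in DG 2 with each library left out.

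Called lists fell to 0 in all comparisons with an estimated correlation. With the number series they were 0 (LPS), 2 (age) and 3 (LPS against age) in CA1 and 3, 8 and 0 in DG. Of these, 1 age list in CA1 (oxidative phosphorylation) and 1 in DG (endothelial cells) were among the lists called without it, and none for LPS or LPS against age. With the dissection score they were 1 for LPS in CA1 and 2 for LPS against age in DG; the oligodendrocyte list with LPS in CA1 (0.921) and the CA1 pyramidal list with age in DG (0.453) then turned downward. Without those libraries they were 6, 15 and 3 in CA1, and 3 for LPS and 11 for age in DG. Without the libraries of high meningeal fibroblast mean the lists were 9 (LPS), 4 (age) and 1 in CA1 and 10, 14 and 3 in DG, and the genes for LPS against age 2 in CA1 and 1 in DG. Without the 2 vehicle libraries of these the age lists in DG were 14, and the endothelial list turned upward (0.217). Single libraries left out gave 0 to 9 (LPS), 1 to 7 (age) and 0 to 3 lists in CA1 and 0 to 4, 4 to 12 and 0 to 7 in DG. The region difference with LPS gave 0 genes with no replicate block, a pseudocount of 5 or the stricter filter, and 2 without the 4 rats of those libraries (0 to 2 with each rat left out); the block changed no age call (0). The correlation of LPS and age changes was -0.14 with split controls in DG, and with single libraries left out it ran from -0.17 to 0.18 in CA1 and 0.26 to 0.38 in DG.

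Of 100 splits of the rats per comparison, the real one included, as many genes came from 100 (LPS, CA1; real 0, highest other 572, which tests nothing), 1 (age, CA1; 2 and 1), 2 (LPS against age, CA1; 1302 and 2050), 3 (LPS, DG; 2 and 40), 3 (age, DG; 2 and 21) and 3 (LPS against age, DG; 2 and 45). Taken singly, few splits gave as many genes for the last 5. That makes chance less likely for each, but with no adjustment over the 14 counts of this kind it is not excluded. Only for age in CA1 did no other split reach the real count. The splits did not keep the number series of the rats, with which the age count was 0 in CA1 and 1 in DG. The age changes in that fit were 2.96 (SE 0.59) for Cdh1 in DG, 1.61 (SE 0.37) for Cdh1 and 0.96 (SE 0.20) for Pbx3 in CA1. Without the series they were 3.43, 2.06 and 1.07, so each kept its direction and was smaller with the series. These genes were chosen in the fit without the series, so the sizes do not decide about it. Few rats carry the age contrast within a series. Replicate 2410 was the only young vehicle rat of series 24, and 2531 and 2532 were the only aged rats of series 25. As many lists came from 84 (LPS; 3 and 25), 74 (age; 4 and 21) and 100 (LPS against age; 0 and 14, which tests nothing) in CA1 and from 98 (1 and 22), 61 (7 and 20) and 95 (1 and 17) in DG, so chance is not excluded for the 5 list counts above 0. For the LPS region difference it was 6 (1 and 1), so chance is not excluded; for age it was 100 (0 and 0), which tests nothing. Other splits gave a median of 7 or 8 lists for LPS and age and 4 for LPS against age. Why some splits gave many more calls than the real one was not tested.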

Other observations

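The tests in this part were chosen after the results were seen. Across the 22 rats, the C3 level after subtraction of the group means was related between CA1 and DG at r = 0.54 (permutation p = 0.0185, adjusted p = 0.0555 over 3 genes) and rho = 0.61 (permutation p = 0.0116, adjusted p = 0.0348), two-sided, with 1e+05 resamples. Without the 2 rats farthest from the median r was 0.66. Within number series it was 0.36 over 8 rats and 0.39 over 10 rats, and the remaining series had 4 rats, too few for a value. A candidate explanation is that the C3 level is a property of the rat; the Pearson value missed the threshold, so this stays open. Over all rats Cdh1 (r = 0.14, adjusted permutation p = 0.891) and Rpl6 (r = 0.024, adjusted permutation p = 0.923) gave no such relation. Within the series of 8 rats and of 10 rats, r was -0.58 and -0.0085 for Cdh1 and 0.53 and -0.10 for Rpl6.

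Across 14637 genes, the LPS effects in CA1 and DG correlated at r = -0.27, and 98.5% of 1000 relabellings of the rats gave a value as high, so r lay below the relabelled range of -0.26 to 0.30. The age effects correlated at r = 0.15, within the relabelled range of -0.20 to 0.31. Genes are not independent replicates.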
